A study of Mus musculus with 16 samples.

How the data were processed

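Total RNA from mouse brain tissue was measured on Illumina bead arrays, with 1 array for each of 5 dorsal controls, 3 ventral controls and 8 tumours. Per the labels, the tissue was flash frozen, a Qiagen kit for lipid-rich tissue was used for RNA extraction, and a biotin label was added by the standard Illumina procedure. The labels number the controls as biological replicates and the tumours as independent tissues. The study's design text counts 10 tumours, of which 8 are analysed here. The labels give each control its region and give no region for a tumour. Which genes were deleted is not given in the sources used here, and neither are the age and sex of the mice.

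Per the file headers, 1 deposited table holds the mean bead intensity of 45281 probes on each array, neither normalized nor background-subtracted, and a detection p-value for each probe on each array. The median intensity was between 125.7 and 141.7 over the 16 arrays. A second table deposited by the authors holds log2 values of 38563 probes. Their method is not given in the sources used here. Across probes, which are not independent replicates, these log2 values correlated with the values computed here at r = 0.999997 to 0.999998 on each array and differed by at most 0.0603, which settles the base of the logarithm.

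All values reported come from the intensity table. They were processed in R 4.3.3 with limma 3.58.1 by neqc, which corrects background by a normal-exponential model fitted from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. Probes with a detection p-value under 0.05 on at least 3 arrays were kept, which left 23131. Gene names came from the platform table, which lists 32109 of the probes, and were updated through Entrez IDs for 32035 of them. The 4989 kept probes without a single gene name were tested only in an alternative. For each gene the probe with the highest mean over all arrays was used, which gave 11755 genes, 4379 of them with more than 1 kept probe. The number of arrays limits the precision of every value. Signals near background limit it further, because an array gives no count of molecules.

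A limma model with 3 group means was fitted to all 16 arrays, followed by empirical Bayes moderation and Benjamini-Hochberg adjustment over the 11755 genes. A gene passed at an adjusted p under 0.05, and a stricter count also asked for a change of at least 2-fold. The contrasts were tumour minus the mean of both control regions, tumour minus dorsal control, tumour minus ventral control, and ventral minus dorsal control. Where a gene was undetected on every array of the lower group, the lowest value of a detected probe on each array stood in for it, and the fold is given as "at least". Errors are standard errors of the limma contrast unless called SD. The word tumours in "tumours above every control" counts tumour arrays whose value exceeded that of each of the 8 control arrays.

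For 33 gene lists with 511 members, fixed before the data were examined, the members past the threshold were counted over all genes and adjusted over the list alone. The 30 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast. An estimated correlation and the fry test stood beside it. List medians over all chips are also given with undetected genes at their bound where this changes the value. A list score is the mean over members of an array's value minus the mean of both control group means. Genes are named by a rule fixed before the data were examined. For the tumours it takes the 10 largest rises and falls that passed against each region separately and were detected on every array of the higher group, the recombined tumour suppressors, the 3 most changed members of each called list and 1 in the other direction, and 1 member of each other list. For the ventral controls it takes the 10 largest differences each way and 2 members of each called list. Other genes, among them the members of a list where 5 or fewer passed, were named after their values were seen.

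The 16 arrays lay on 3 chips. Chip 1 held 3 tumours, 1 dorsal and 1 ventral control, chip 2 held 2 tumours and 3 dorsal controls, and chip 3 held 3 tumours, 1 dorsal and 2 ventral controls. The contrasts were repeated with chip as a block and within each chip. Alternatives covered background correction, normalization, the authors' log2 values, the detection filter, the choice of probe, array weights, the variance prior, a block on the replicate number, the weighting of the controls and leaving out each array in turn. Groupings of the same arrays into other groups of the same sizes were counted, 100 drawn with a fixed seed for the tumour contrasts and all 56 for the controls.

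The procedure was tested on simulated data with 11755 genes, 200 of them changed. For tumour against the mean of both controls it recovered 22.4% of the 1.5-fold, 76.1% of the 2-fold and 93.9% of the 4-fold changes, with 10 false calls. For tumour against dorsal control it recovered 23.9%, 70.1% and 92.4% of these, with 10 false calls. For tumour against ventral control the shares were 8.96%, 53.7% and 87.9%, with 8 false calls. For ventral against dorsal control they were 4.48%, 44.8% and 86.4%, with 5 false calls. Of simulated lists, the shifted one passed camera at an adjusted p of 1.52e-56 and 0 of 29 unshifted lists passed. Genes varied independently in this simulation, so it cannot show how often a list of correlated genes passes by chance.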

Results

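Messenger RNA was profiled in brain tumours from mice in which an inducible Cre recombinase was used to delete tumour suppressor genes. The tumours are called high-grade glioma in the title of the study. The 8 tumours were compared with 5 samples of dorsal and 3 samples of ventral brain from control mice. Between 17565 and 20430 of the 45281 probes were detected on an array, which is 38.8% to 45.1%.

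Tumours and controls formed separate groups. The first principal component held 53.9% of the variance and set every tumour apart from every control, and the second held 10.3% and set the ventral apart from the dorsal controls. Pairs of tumours correlated across genes at r = 0.878 to 0.983, pairs of dorsal controls at 0.943 to 0.991 and pairs of ventral controls at 0.985 to 0.990. A tumour and a dorsal control correlated at 0.768 to 0.838, and a tumour and a ventral control at 0.797 to 0.859.

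**Figure D1:**
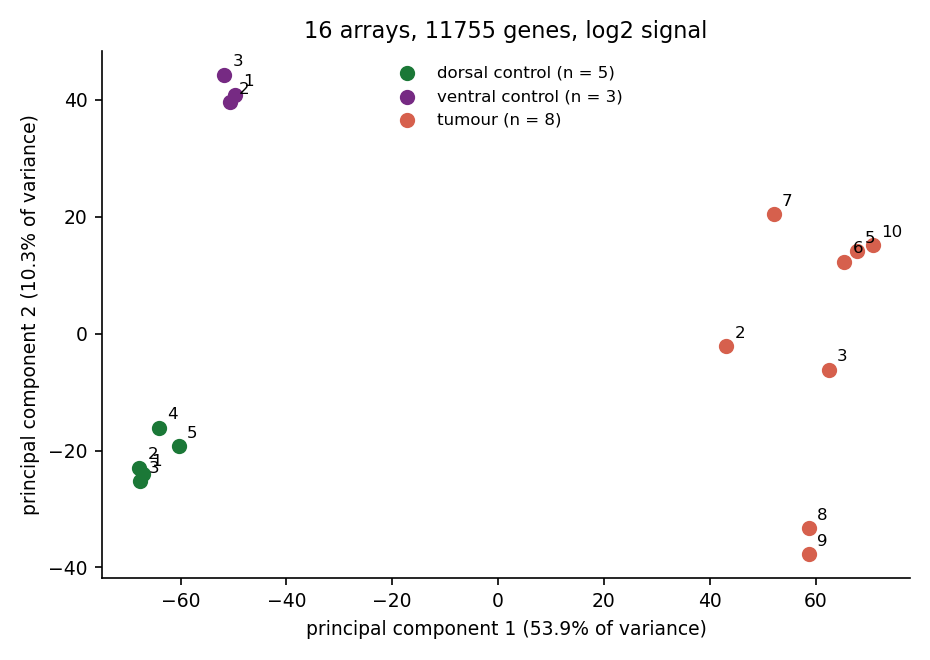
The arrays on the first and second principal components of the log2 signals, with the share of variance on each axis, colour for the group and the replicate number of the labels beside each point. The 8 tumours lie on the right, and the 3 ventral controls lie above the 5 dorsal controls on the left.

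Of the tumour suppressors that mouse models of glioma commonly delete, Nf1, which encodes a negative regulator of RAS, was measured. Its log2 signal was 5.35 ± 0.30 (SD, n = 5) in dorsal controls, 5.82 ± 0.17 (SD, n = 3) in ventral controls and 4.96 ± 0.26 (SD, n = 8) in tumours. Against the mean of both regions it fell by 0.62 ± 0.14 on the log2 scale (limma adjusted p = 0.00146), and 3 of 8 tumours lay below every control. The difference against dorsal control alone, -0.39, did not pass. The signal is close to background, with detection on 5 of 8 tumours, and where the probe lies relative to any deleted exon is not given in the sources used here.

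The comparison of tumours with the mean of both control regions asks which transcripts set the tumours apart from normal brain when neither region is favoured. Genes of cell division, of oligodendrocyte progenitors, of interferon response, of macrophages and of extracellular matrix were higher in the tumours, and neuronal genes were lower, by camera at a preset correlation. With an estimated correlation 0 lists passed after adjustment and 6 at an unadjusted p under 0.05, and by fry 20 did. Among the genes that passed against each region separately and were detected on every array of the higher group, the largest rise was that of Gpnmb, a glycoprotein of macrophages and some tumours, at 32.1-fold (log2 5.00 ± 0.48, adjusted p = 3.46e-07). Vim, an intermediate filament of immature and reactive glia, rose 29.1-fold (4.86 ± 0.33, adjusted p = 1.19e-08), and Lyz2, a lysozyme of myeloid cells, 28.4-fold (4.83 ± 0.46, adjusted p = 3.66e-07). The largest falls among such genes were those of Nrsn2 (-4.89 ± 0.34, adjusted p = 1.31e-08), Scn4b, a sodium channel subunit (-4.88 ± 0.43, adjusted p = 1.7e-07), and Lin7b, a synaptic scaffold (-4.85 ± 0.29, adjusted p = 2.49e-09). Each of these 6 genes lay beyond every control in 8 of 8 tumours.

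The other genes among the largest rises were Cdca3 (at least 22.5-fold), Pbk (at least 24.2-fold), Prc1 (4.77), Traf4 (4.72) and Usp18 (4.70), with the histone genes H2ac15 (4.91) and H2ac12 (4.88). The probes of these histone genes can also bind transcripts of related histone genes. The other large falls were in Hpca (-4.84), Sst (-4.83), Gng13 (-4.80), Slc17a6 (-4.75), Lamp5 (-4.69), Sncb (-4.61) and Scn2b (-4.60). A second probe of Gpnmb gave 2.15, one of Cdca3 2.73, one of Scn4b -0.60 and one of Scn2b -0.94, with -4.05 from another of Scn2b, so the size of a change depends on the probe. Second probes likewise gave 0.11 for Cd44, -0.04 for Pdgfra and 0.56 for Sox4, where the probes used gave 3.69, 2.90 and 3.74, and another of Cd44 gave 2.20. Weaker changes came as well from other probes of Tnc (0.84 and 1.34, beside 4.34), Oasl2 (0.55 and 1.45), Thy1 (-0.89), Angpt2 (0.48), Lyz2 (2.60), Nes (1.80), Pdyn (-1.61) and Psmb8 (1.43). In all, 6348 of 11755 genes (54%) passed, 3209 higher and 3139 lower. Of these, 3070 differed at least 2-fold, 1468 higher and 1602 lower. Without background correction 1410 differed at least 2-fold. With median scaling in place of quantiles 43.1% of the genes called were higher, against 50.6%. With chip as a block 6341 passed. Of the genes called, 99.45% had the same sign within chip 1 and 99.34% within chip 3, the chips that hold all 3 groups. These arrays also gave the calls, so the shares are no independent test.

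Cell cycle genes rose in all tumours. Of 29 measured, 26 rose and 0 fell (26 and 0 adjusted over the list alone), with a median log2 change of 2.76, or 2.31 with undetected genes at their bound. The list score of each of the 8 tumours exceeded that of every control. Prc1, which bundles spindle microtubules, rose by 4.77 ± 0.25 (adjusted p = 7.16e-10). Cdc20, an activator of the anaphase-promoting complex, rose by 4.62 ± 0.19 (adjusted p = 1.03e-10), and Cenpa, the centromeric histone, by 4.60 ± 0.28 (adjusted p = 3.03e-09). The list passed camera at an adjusted p of 3.3e-13 (adjusted p = 0.208 with an estimated correlation).

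Oligodendrocyte progenitor and proneural genes rose in 16 of 19 cases and fell in 0 (16 and 0 adjusted over the list alone), with a median of 1.83 and an adjusted camera p of 2.45e-06 (adjusted p = 0.232 with an estimated correlation). Lhfpl3 rose by 3.37 ± 0.42 (adjusted p = 5.05e-06), and Olig2, a transcription factor of the oligodendrocyte lineage, by 3.28 ± 0.38 (adjusted p = 2.47e-06). Matn4 rose by 2.95 ± 0.52 (adjusted p = 0.000183) and exceeded every control in 7 of 8 tumours. Of 18 neural stem and progenitor genes, 12 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 1.14 and an adjusted camera p of 0.00172 (adjusted p = 0.208 with an estimated correlation). Sox4 rose by 3.74 ± 0.23, Nes, the intermediate filament of neural progenitors, by 3.52 ± 0.41, and Sox11 by 2.75 ± 0.33. The member that fell was Dlx1, a transcription factor of forebrain interneuron progenitors (-3.33 ± 0.48, adjusted p = 2.63e-05).

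Neuronal genes fell together. All 14 measured pan-neuronal genes fell (14 lower and 0 higher adjusted over the list alone), with a median of -3.32 and an adjusted camera p of 5.63e-08 (adjusted p = 0.208 with an estimated correlation). The largest changes were those of Vsnl1 (-4.48 ± 0.57), Stmn2 (-4.04 ± 0.62) and Thy1 (-3.91 ± 0.54). The pan-neuronal score of the tumours ran from -4.16 to -1.59, so tumours differed in how far these genes fell. All 11 glutamatergic genes fell (11 lower and 0 higher adjusted over the list alone), with a median of -2.12 and an adjusted camera p of 5.13e-05 (adjusted p = 0.232 with an estimated correlation), among them Slc17a6, Nrgn (-3.92 ± 0.62) and Camk2a (-3.84 ± 0.62). All 10 GABAergic genes fell (10 lower and 0 higher adjusted over the list alone), with a median of -3.21 and an adjusted camera p of 0.000505 (adjusted p = 0.253 with an estimated correlation), among them Sst, Pvalb (-4.60 ± 0.67) and Slc32a1, the vesicular GABA transporter (-4.39 ± 0.64). On chip 3, Slc17a6 differed from dorsal control by 0.59 and Dlx1 by 0.09, against -3.00 and -2.63 over all arrays. The only dorsal control on that chip was dorsal control 5. Its signals were 6.00 for Slc17a6 and 6.22 for Dlx1, against 8.36 to 11.05 and 8.10 to 8.54 in the other dorsal controls. An effect of the chip cannot be told apart from this array.

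Regional neuron genes fell in part. Of 11 genes of striatal projection neurons, 7 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -1.81 and an adjusted camera p of 0.0443 (adjusted p = 0.648 with an estimated correlation, 0.0641 with median scaling). Against ventral control alone 3 of these fell and the list did not pass (median -0.86, adjusted p = 0.152). Among them were the neuropeptide genes Tac1 (-4.31 ± 0.72) and Pdyn (-3.76 ± 0.59), and Pde1b (-2.63 ± 0.57). The striatal score was 2.39 in dorsal control 4 and 3.10 in dorsal control 5, against -1.25, -1.18 and -1.15 in the other dorsal controls. The striatal list median, tumour minus the mean of both regions, was -0.59 within chip 1 and -3.58 within chip 3. The only dorsal control was dorsal control 1 on chip 1 and dorsal control 5 on chip 3. Of 18 genes of thalamus, hypothalamus and brainstem, 11 fell and 3 rose (11 and 3 adjusted over the list alone), with a median of -1.50 and an adjusted camera p of 0.0466 (adjusted p = 0.208 with an estimated correlation, 0.0866 with median scaling). Against dorsal control alone 6 of these rose and 2 fell, with a median of 0.16 (0.12 at bounds), and the list did not pass (adjusted p = 0.546). Pmch and Hcrt, hypothalamic neuropeptides detected in 0 of 8 tumours, were at least 23.5-fold and 11.5-fold lower than the mean of both regions. Hcrt was undetected on 5 of 5 dorsal controls as well, so its fall is one against ventral tissue. Pmch and Hcrt did not pass against 8 controls taken as 1 group (adjusted p = 0.0519 and 0.0776). The members that rose were Prkcd, Tph2 and Hoxa5, a homeobox gene of the hindbrain and spinal cord that was at least 10.5-fold higher.

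Immune genes rose. Of 10 monocyte and macrophage genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 2.13 (1.98 at bounds) and an adjusted camera p of 0.000832 (adjusted p = 0.272 with an estimated correlation). Beside Gpnmb and Lyz2, Lgals3 rose by 4.61 ± 0.35 (adjusted p = 3.51e-08). All 13 interferon response genes rose (13 and 0 adjusted over the list alone), with a median of 3.20 (2.78 at bounds) and an adjusted camera p of 6.54e-08 (adjusted p = 0.208 with an estimated correlation). Usp18, a protease that removes ISG15, rose by 4.70 ± 0.40, Oasl2 by 3.80 ± 0.30 and Gbp3 by 3.71 ± 0.25. Of 14 genes of antigen processing and MHC class II, 12 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 1.75 and an adjusted camera p of 5.13e-05 (adjusted p = 0.272 with an estimated correlation). H2-Ab1 rose by 3.43 ± 0.62, Psmb8 by 3.33 ± 0.28 and H2-D1 by 3.18 ± 0.30, the last with a probe that transcripts of related class I genes can bind. The scores of these 3 lists exceeded every control in 8 of 8 tumours. Of 14 microglia genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone), with C1qb at 2.34 ± 0.39. The list did not pass camera (median 0.85, or 0.79 at bounds, adjusted p = 0.0612). Its median was -0.10 within chip 1 and 1.51 within chip 3.

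Of 17 genes of extracellular matrix and the mesenchymal state, 14 rose and 1 fell (14 and 1 adjusted over the list alone), with a median of 2.64 and an adjusted camera p of 5.26e-05 (adjusted p = 0.312 with an estimated correlation). Besides Vim, Tnc, a matrix glycoprotein, rose by 4.56 ± 0.54 and Cd44, a hyaluronan receptor, by 3.69 ± 0.36, while Chil1 fell by 1.09 ± 0.23. Of 13 RAS-MAPK output genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.99 and an adjusted camera p of 0.0466 (adjusted p = 0.49 with an estimated correlation). Ccnd1, cyclin D1, rose by 3.73 ± 0.40, Etv4 by 3.37 ± 0.43 and Spry4, a feedback inhibitor of the pathway, by 1.83 ± 0.51. Ccnd1 lies in a stretch of neighbouring genes with high signals in tumours 6 and 7, but was also 14.19 in tumour 3, which had no such stretch. Of 17 oxidative phosphorylation genes, 12 fell and 0 rose (13 and 0 adjusted over the list alone), with a median of -0.46 (-0.42 at bounds) and an adjusted camera p of 0.00172 (adjusted p = 0.208 with an estimated correlation). The largest falls were those of Cox6c (-0.74 ± 0.15), Cox5a (-0.70 ± 0.15) and Cycs, cytochrome c (-0.69 ± 0.14).

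**Figure D2:**
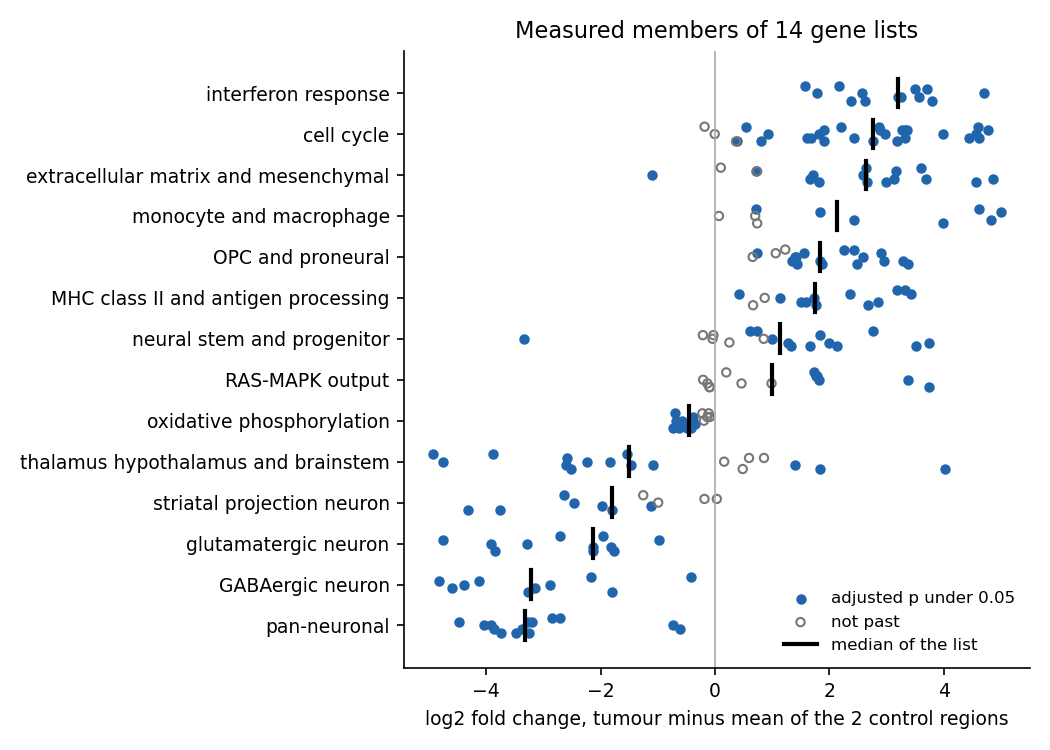
Log2 fold change of each measured member (points) of the 14 lists that passed, tumour minus the mean of both control regions, with filled points for an adjusted p under 0.05 and a black line at the list median. Medians run from -3.32 for pan-neuronal to 3.20 for interferon response genes.

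The lists of other cell types did not pass. Of 15 astrocyte genes, 8 fell and 1, Gfap, rose (8 and 1 adjusted over the list alone), with the largest change in the neurotensin receptor Ntsr2 (-3.04 ± 0.26, adjusted p = 1.13e-07; list adjusted p = 0.222). Of 12 myelin genes 6 fell and 0 rose (6 and 0 adjusted over the list alone), with Mobp at -3.68 ± 0.75 (adjusted p = 0.000624; list adjusted p = 0.128), and the myelin score of the tumours ran from -3.43 to 0.92. Of 14 endothelial genes Vwf rose (1.38 ± 0.38) and Flt1 fell (list adjusted p = 0.906), and of 8 pericyte genes 0 passed, with Vtn at -0.92 ± 0.45 (adjusted p = 0.0929; list adjusted p = 0.906). Of 11 angiogenesis genes Angpt2 (3.28 ± 0.38), Mcam, Nid2 and Col4a1 rose and Vegfa fell (list adjusted p = 0.289). Of 6 neutrophil genes Lcn2 rose, at least 11.7-fold (list adjusted p = 0.33), and of 2 T and NK cell genes Ccl5 rose, at least 5.68-fold. Of 6 blood genes the globins Hbb-bs (-3.97 ± 1.05), Hbb-bt and Hba-a1 fell (list adjusted p = 0.198). Of 9 choroid plexus and ependyma genes Clic6, Rarres2 and Kl (-0.52 ± 0.12, or -0.24 with signals below background raised to it) fell (list adjusted p = 0.271). Of 11 meninges and fibroblast genes Pdgfra (2.90 ± 0.51), Bgn and Aebp1 rose and Slc22a6 fell (list adjusted p = 0.348).

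Of 12 cortex and hippocampus genes 5 fell and 1, Lmo4, rose (4 and 1 adjusted over the list alone, list adjusted p = 0.246). Mef2c changed by -1.52 ± 0.35 but lay below every control in 1 of 8 tumours. It differed from ventral control by -0.03 and 0.14 within chips 1 and 3. Against ventral control 0 genes of the list fell and 1 rose (median -0.25, camera adjusted p = 0.954). Of 12 p53 targets, Cdkn1a, Fas, Bbc3, Trp53inp1 and Mdm2 rose, and Zmat3 (-1.11 ± 0.12) and Ccng1 fell (list adjusted p = 0.349). Of 12 genes of hypoxia and glycolysis, 7 fell, with Aldoa at -1.94 ± 0.30, and Ldha and Egln3 rose (list adjusted p = 0.175). Of 9 cholesterol synthesis genes Msmo1 (-1.54 ± 0.18), Fdps and Mvd fell (list adjusted p = 0.289). Of 11 immediate early and heat shock genes, Arc, Npas4 (at least 2.27-fold), Hspa1a and Dnajb1 fell and Egr2 rose (list adjusted p = 0.348). Egr2 lay above every control in 2 of 8 tumours. It differed from dorsal control by 0.85, -0.10 and -1.03 within chips 1, 2 and 3, and from ventral control by 2.95 and 2.61 within chips 1 and 3. Of 9 genes on the list for the classical glioma subtype, Cdkn2a (at least 14.2-fold), Nes, Smo and Lfng rose and Fgfr3 fell (list adjusted p = 0.0646). The list did not separate genes gained from genes lost in that subtype, so the rise of Cdkn2a is no sign of it. Of 3 sex-linked genes Uty, detected in 0 of 8 tumours, 1 of 5 dorsal and 3 of 3 ventral controls, was at least 1.05-fold lower (limma adjusted p = 0.0355; 0 genes adjusted over the list alone). For the lists of this and the preceding paragraph with no count of their own, the members adjusted over the list alone were the same in number, except that Slc22a6 did not pass.

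Altogether 14 lists passed. Because 27 of 100 groupings of the same arrays, the real one included, gave as many, their number alone does not set the tumours apart from chance. The other groupings had a median of 11 called lists. The fry test, which called more, does not compare a list with other genes. With a block on the replicate number of the labels, Nrgn, Mef2c, Vwf, Spry4, Cycs and Uty did not pass (limma adjusted p = 0.053, 0.0574, 0.055, 0.104, 0.0684 and 0.148).

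The comparisons with each region alone ask how far the changes hold whichever region a tumour came from. Against dorsal control alone 5890 genes passed (50.1%; 3051 higher and 2839 lower), 3242 of them at 2-fold and 1560 without background correction. With median scaling 42.3% of the genes called were higher, against 51.8%. Glutamatergic genes fell in 11 of 11 cases, with a median of -3.38 and an adjusted camera p of 6.36e-07 (adjusted p = 0.231 with an estimated correlation). Immediate early genes fell in 6 of 11 (camera adjusted p = 0.037, or 0.502 with an estimated correlation). On the classical glioma list 5 of 9 genes rose, Cdkn2a among them (camera adjusted p = 0.0374, or 0.231 with an estimated correlation). Against ventral control alone, 4784 genes passed (40.7%; 2306 higher and 2478 lower), 2942 of them at 2-fold and 1376 without background correction. With median scaling 44.2% of the genes called were higher, against 48.2%. There, 10 of 18 genes of thalamus, hypothalamus and brainstem fell and 3 rose (median -2.15, adjusted p = 0.000235; adjusted p = 0.023 with an estimated correlation), and glutamatergic genes fell in 4 of 11 (median -0.87, adjusted p = 0.0427; adjusted p = 0.585 with an estimated correlation). Microglia genes rose in 6 of 14 (adjusted p = 0.0233; adjusted p = 0.681 with an estimated correlation), and RAS-MAPK genes in 7 of 13 (adjusted p = 0.00216; adjusted p = 0.307 with an estimated correlation). Some lists passed against 1 region alone. Genes of thalamus, hypothalamus and brainstem did not pass against dorsal control, where the median had the opposite sign. Nor did RAS-MAPK genes there, with 6 higher and 2 lower (median 0.50, adjusted p = 0.383), or microglia genes (median 0.57, or 0.48 at bounds, adjusted p = 0.23). Against ventral control, immediate early genes did not pass and their direction turned, with 3 higher and 1 lower (median 0.24, adjusted p = 0.571). Striatal genes and genes of the classical list (median 0.38, or 0.20 at bounds, adjusted p = 0.148) did not pass there either. Between ventral and dorsal control the thalamus, immediate early and RAS-MAPK lists passed at the preset correlation, as given with the regional background, while the microglia, striatal and classical lists did not (adjusted p = 0.251, 0.251 and 0.51), so no difference between regions was shown for these.

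Against both regions in the same direction 3867 genes passed, 2022 higher and 1845 lower, and 41 passed in opposite directions. Independent lists of these sizes would share 599 higher and 598 lower genes. The contrasts share the 8 tumours, which raises the overlap. In 20 simulations with unchanged groups, lists of the same sizes taken by rank shared on average 974 higher and 989 lower genes, a value that leaves out any effect. With 4 tumours compared with dorsal and the other 4 with ventral control, 1535 higher and 1537 lower genes were shared, where 501 and 505 would be by the sizes of the lists. With chip as a block 5684 and 4700 genes passed against dorsal and ventral control. Of the genes called against dorsal control 99.1%, 99.76% and 96.86% had the same sign within chips 1, 2 and 3. Of those called against ventral control 99.96% and 100% did within chips 1 and 3. Here too the arrays of the chips gave the calls.

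**Figure D3:**
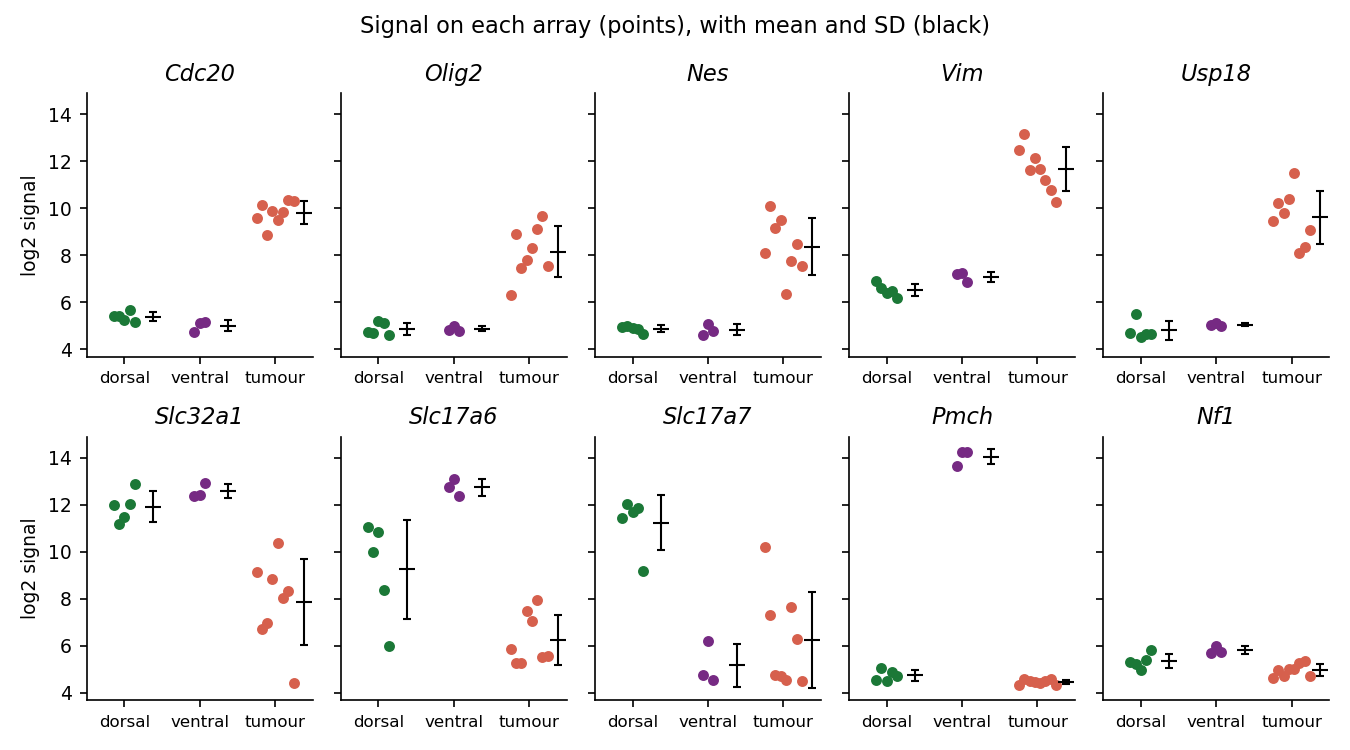
Log2 signal of 10 genes on each array (points) of the dorsal controls (n = 5), ventral controls (n = 3) and tumours (n = 8), with the group mean and SD in black. Cdc20, Olig2, Nes, Vim and Usp18 lie higher in tumours than in every control, and Pmch is high in the 3 ventral controls alone.

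The ventral and dorsal controls give the regional background of these comparisons. Pmch, melanin-concentrating hormone, was at least 545.3-fold higher in ventral control (limma adjusted p = 8.32e-16), with detection on 2 of 5 dorsal controls, Hcrt, orexin, at least 167.2-fold and Gal, galanin, at least 47.7-fold. Slc17a7, the vesicular glutamate transporter of cortex, differed by -6.09 ± 1.11 (adjusted p = 0.00197), and Egr3, an immediate early transcription factor, by -5.11 ± 0.65 (adjusted p = 8.23e-05). For each of these 5 genes the 3 ventral controls lay beyond every dorsal control. A second probe of Pmch gave 3.69 and one of Egr3 -0.12.

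Further genes higher in ventral tissue were Igsf1 (5.99), Dlk1 (5.67), Oxt (5.64, with an SD of 4.38 among the ventral controls), Gpx3 (5.21), Calb2 (5.14), Trh (5.14) and Tsr3 (5.20). A second probe of Tsr3 gave 5.36 and another -1.81, so its direction depends on the probe. The other probes of Igsf1 gave 2.44 and 6.38. Further genes lower in ventral tissue were Gabrd (at least 31.4-fold), Kcnh3 (at least 19.2-fold), Arc (-4.75), Ddn (-4.55), Itpka (-4.54), Epop (-4.20), Arpp21 (-4.19, with -2.11 to -0.75 from other probes) and Nrgn (-4.16). In all 1111 genes passed (9.45%; 606 higher and 505 lower in ventral), 737 of them at 2-fold, and 746 passed with chip as a block. With only the compared groups in the fit 2795 passed, and without background correction 359 differed at least 2-fold. With median scaling 47.6% of the genes called were higher in ventral tissue, against 54.5%. Without ventral control 1, 2 or 3 the count was 615, 691 or 576, and it was 4192 with array weights. Within chips 1 and 3, 99.91% and 99.19% of the genes called had the same sign. These arrays also gave the calls, and chip 1 holds 1 array of each region, so the shares are no independent test. Differences within these chips correlated across genes with the main ones at r = 0.89 and 0.796.

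Genes of thalamus, hypothalamus and brainstem were higher in ventral tissue in 11 of 18 cases and lower in 0 (12 and 0 adjusted over the list alone), with a median of 1.92 and an adjusted camera p of 7.83e-13 (adjusted p = 4.8e-05 with an estimated correlation). Glutamatergic genes were lower in 9 of 11 and higher in 1, Slc17a6 (9 and 1 adjusted over the list alone), with a median of -2.76 and an adjusted camera p of 3.87e-08 (adjusted p = 0.163 with an estimated correlation). Immediate early and heat shock genes were lower in 6 of 11 and higher in 0 (7 and 0 adjusted over the list alone; median -1.78, adjusted p = 2.36e-05; adjusted p = 0.221 with an estimated correlation), with Arc and Egr2 (-3.05 ± 0.70, adjusted p = 0.0102). Of 12 cortex and hippocampus genes 5 were lower and 0 higher (5 and 1 adjusted over the list alone), with a median of -0.66 (-0.54 at bounds), Mef2c at -3.76 ± 0.50 and Tbr1 at -3.64 ± 0.70 (adjusted p = 0.0047; adjusted p = 0.409 with an estimated correlation). Of 13 RAS-MAPK genes 3 were lower, Dusp5 (-2.39 ± 0.34), Dusp6 (-1.78 ± 0.46) and Spred2 (4 adjusted over the list alone; median -0.52, adjusted p = 0.00284; adjusted p = 0.409 with an estimated correlation). Of 9 choroid plexus and ependyma genes 4 were higher, Clic6 (3.09 ± 0.83), Dynlrb2 (2.64 ± 0.67), Kl and Sostdc1, 5 adjusted over the list alone, with a median of 0.87, or 0.39 at bounds (adjusted p = 0.00685; adjusted p = 0.0819 with an estimated correlation). With chip as a block Dusp6, Egr2, Clic6 and Dynlrb2 did not pass (adjusted p = 0.0768, 0.0555, 0.132 and 0.0602), and with a block on the replicate number Egr2 and Oxt did not (0.0543 and 0.0653).

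The dorsal controls were not uniform, as their striatal scores show. The striatal list median for ventral minus dorsal was 0.57 within chip 1, with dorsal control 1, and -3.91 within chip 3, with dorsal control 5. Of the 56 groupings of the control arrays, the real one included, 18 gave as many called lists as the 6 found here, so that number alone does not exclude chance.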

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

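The comparison of each sample with the rest of its group was set before the data were examined, while Egfr was singled out after its values were seen, and the tests on it were written before their results were. Among 248 groups of values, 22 held a sample far from the others of its group, where about 12 would by chance at 1 in 20. The 22 include Egfr, which was picked for its values, and the groups share arrays and in part genes. The excess over 12 is therefore no test against chance.

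Tumour 5 carried high Egfr, the gene of the epidermal growth factor receptor, at a log2 signal of 11.13 against 5.89 to 7.93 in the other tumours. Its score for genes of the classical glioma subtype, a list that holds Egfr, was 2.00, against 0.55 to 1.21 in the other tumours. More astrocytes in this piece of tissue are argued against by 2 tumours that had a higher astrocyte score and Egfr more than 2 lower on the log2 scale. A gain of the region around Egfr may still account for it and was left undecided by the 10 nearest measured neighbours. Their median difference from the median of the other tumours was 0.485, at percentile 93.9 of such windows. This lies between the bounds set for and against a gain. Single neighbours ran from -2.39 (Grb10) to 1.20 (Etaa1), so they were not raised as a whole. The design gives no group that sets tumour 5 apart, so no biological explanation that the design names was tested.

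Tumour 2 had higher scores of some neuronal lists, of macrophage genes and of endothelial genes than the other tumours. Its glutamatergic score was -0.98, against -3.72 to -2.47 in the others, and its cortex and hippocampus score was 0.14, against -0.86 to -0.46. Its Mef2c signal was 10.16, its Gng13 signal 9.82, its Itpka signal 8.19 and its Kcnh3 signal 6.11. Its monocyte and macrophage score was 4.43, against 1.57 to 2.66, and its endothelial score was 1.62, against -0.52 to 0.09 in the other tumours and at most 0.28 in the controls. Tumour 9 had a Kl signal of 5.03, against 4.42 to 4.61 in the other tumours, and Kl was detected on 1 tumour.

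Dorsal control 5 stood apart from the other dorsal controls in cortical genes. Its Tbr1 signal was 5.77, against 9.31 to 9.70, its Slc17a7 signal 9.19, against 11.46 to 12.02, and its Dlx1 signal 6.22, against 8.10 to 8.54. Its glutamatergic score was 0.0095, against 1.16 to 1.53. Its Cenpa signal was 6.39, its Sox4 signal 6.00 and its Traf4 signal 5.44, each below the other dorsal controls. Dorsal control 4 had a Gpx3 signal of 6.86, against 5.41 to 5.63, and a Pbk signal of 5.51, against 4.38 to 4.63. Dorsal control 2 had a Usp18 signal of 5.50 and a Dynlrb2 signal of 5.96, each above the other dorsal controls.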

How the results depend on the processing

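Averaging tumours 8 and 9, averaging tumours 6 and 7 as well, and leaving out dorsal controls 4 and 5 were chosen after seeing the data, and the other alternatives were fixed before. Leaving out 3 tumours by their myelin gene levels was also tried after seeing the data, and its values are not used because it picks samples by an outcome. Of the counts under the alternatives, 264 were within 1.5 times the reported value and 22 were not, and under these alternatives no named gene changed direction. Outside them, other probes of Tsr3 and Pdgfra turned. So did some differences within a chip, such as those of Slc17a6 and Dlx1 on chip 3, where the only dorsal control was dorsal control 5. Without background correction the genes at 2-fold were 1410, 1560, 1376 and 359 for tumour against the mean of both controls, dorsal control, ventral control, and ventral against dorsal control, since uncorrected background shrinks folds. With every detected probe on its own, which tests more units, the counts in that order were 11736, 10830, 8517 and 1891, at 2-fold 5278, 5598, 5009 and 1214, and 6875 against both regions. For ventral against dorsal control, 2795 genes passed with only the compared groups in the fit, which leaves out the more variable tumours, and array weights gave 4192 and, at 2-fold, 1182; the cause of the latter was not tested. Leaving out each array in turn gave 576 to 1261 genes and 480 to 787 at 2-fold for this contrast, lowest without ventral control 3. It gave 5716 to 6352 for tumour against the mean of both controls, 5366 to 5983 against dorsal, 3587 to 4932 against ventral control and 3030 to 3966 against both regions.

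In the order above, camera with an estimated correlation called 0, 0, 1 and 1 lists after adjustment and 6, 5, 7 and 4 at an unadjusted p under 0.05, and fry 20, 18, 17 and 6. The matrix list for ventral against dorsal control, with a median of 0.12 and a mean of -0.07, turned direction under fry (adjusted p = 0.997) and median scaling (0.994), and the hypoxia list, with a median of -0.05 and a mean of 0.05, under fry (0.997). Neither had passed, and the cause was not tested. Median scaling in place of quantiles moved the median change of all genes from 0.01 to -0.10 for tumour against the mean of both controls and from 0.03 to -0.12 against dorsal control. Under it the microglia list passed (adjusted p = 0.0389), which with an estimated correlation under quantile normalization did not (0.648). Chip as a block gave 6341, 5684, 4700 and 746 genes. Residuals of samples with the same replicate number correlated across genes at r = -0.06 to 0.14. Pairs with different numbers were not set beside them, so whether the numbers of the labels pair the samples is not settled. A block on that number, which costs degrees of freedom, gave 4748, 4771, 3736 and 1082. Under it 8 named genes lost their call with the direction unchanged, for tumour against the mean of both controls Nrgn (-2.44), Mef2c (-0.98), Vwf (1.81), Spry4 (1.27), Cycs (-0.56) and Uty, and between the regions Oxt (5.63) and Egr2 (-2.73). Calls were also lost without background correction by Uty (adjusted p = 0.0843) and Egr2 (0.0717), without a filter on dim probes by Clic6 (0.0515), with the mean of a gene's probes by Dusp6 (0.0783), and with tumours 8 and 9 averaged by Uty (0.051). With tumours 8 and 9 averaged the counts were 6182, 5863, 4791 and 1131, with 6 and 7 averaged too 6100, 5758, 4733 and 1154, and without dorsal controls 4 and 5 they were 5959, 4936, 4685 and 1046. Without these controls Egr2 and Dynlrb2 did not pass between the regions (adjusted p = 0.0555 and 0.0747). Uty, Clic6, Dusp6 and Dynlrb2 also lost their call when single arrays were left out, with adjusted p of 0.112 for Clic6, 0.115 for Dusp6 and 0.0959 for Dynlrb2 without ventral control 3. Vtn passed with array weights (adjusted p = 0.0125), without tumour 2 (0.0298) and without tumour 10 (0.00524). Signals near background limit the folds of genes undetected in a group, which are bounds.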

Other observations

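The test of the number of Hox and Engrailed genes, both tests of the library and the chip of tumours 8 and 9, the lists of Hox, caudal neuron and forebrain genes, and the scan of neighbouring genes were chosen after the values were seen. Kmt2b was singled out after its own values were seen, while the test on its neighbours was written before its result.

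Some homeobox genes of the hindbrain and midbrain were higher in the tumours. En1, a transcription factor of the midbrain and hindbrain, was at least 18.8-fold higher (limma adjusted p = 4.76e-08), undetected on 8 of 8 control arrays and detected on 8 of 8 tumours. En2 rose by 3.04 ± 0.20 (adjusted p = 7.92e-09). Of 17 measured Hox genes, Hoxa2, Hoxa4, Hoxa5 and Hoxa7 rose, Hoxd11 fell and 12 did not pass. Of 7 genes of forebrain identity, Dlx1 (-3.33), Fezf2 (-2.12), Otx1 (-1.26) and Nkx2-1 (-1.08) fell and 0 rose, with a median of -1.08. Fezf2 was 6.11 to 8.04 in tumours and 7.25 to 7.83 in ventral controls, so its fall is mainly one against dorsal tissue. Nkx2-1 was 4.55 to 4.86 in tumours and 4.67 to 5.81 in dorsal controls, so its fall is mainly one against ventral tissue.

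Tumours differed in genes of receptors and cell cycle control. Pdgfra, a growth factor receptor of oligodendrocyte progenitors, had log2 signals of 8.21 in tumour 5 and 12.82 in tumour 8. Gpr17, a receptor of committed progenitors, was between 6.69 and 12.76 in tumours, and Mbp, a myelin protein, between 7.33 and 14.02. Cdk4, a kinase that drives entry into S phase, was 12.28 in tumour 2 and 9.04 in tumour 9, against 7.08 to 7.77 in controls, and rose by 3.17 ± 0.40 (limma adjusted p = 6.57e-06). Cd74, the MHC class II invariant chain, was 12.38 in tumour 5 and 6.39 in tumour 8. Hbb-bs was 14.25 in tumour 6 and 5.19 in tumour 9.

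In 7 of 8 tumours and 0 of 8 controls, stretches of neighbouring measured genes stood far above the other arrays of the group. With windows of 11 genes and a median difference above 1.5 on the log2 scale, tumour 2 had a stretch around Pip4k2c (2.26), next to Cdk4, and tumour 5 one around Ppfibp1 (3.30), with Med21 at 11.85 and Stk38l at 10.18. Tumours 6 and 7 had stretches around Cttn (2.29) and Ppfia1 (2.21), which hold Ccnd1, at 14.74 and 14.23. Tumour 10 had one around Ikbkg (4.07), whose signal was 12.39 against 7.26 to 8.41 in the other tumours. Tumour 3 had none, with a highest window of 1.14, and the highest window of a control was 0.995. In tumour 3 Ccnd1 was nonetheless 14.19 and Cdk4 11.57, so high signals of these genes were also seen without a stretch. Neighbouring genes can share regulation, as in a window of MHC genes around Psmb8 (1.52) in tumour 2 and in 1 of histone genes around H2bc4 (-1.50) in tumour 8.

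The Hox and Engrailed pattern was set against technical and biological explanations. A single cross-reacting probe or gene is argued against by 6 genes, each with its own probe, that passed and were higher against both controls; an earlier form of this test asked for at least 2 Hox clusters, which was not met, since all 4 Hox genes belong to the Hoxa cluster. A single tumour library is argued against as well, since the same 4 Hox genes passed and were higher whichever tumour was left out. Normal hindbrain or spinal cord tissue in the tumour pieces cannot be excluded, because the 5 measured caudal neuron genes had a median change of -0.521 with a bootstrap SE of 0.704, or -0.0922 with undetected genes at their bound, of which Tph2 (at least 3.4-fold) rose and Glra1, Chat and Uncx fell. The labels give no region for the tumours, so a hindbrain origin may also account for the pattern and was not tested.

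Tumours 8 and 9, which the labels call independent, were the most alike of the 28 tumour pairs, at r = 0.983, with 0.963 for the next pair, tumours 6 and 7. Deposit of 1 library under both numbers is argued against by 44 genes that differ by more than 2 on the log2 scale, such as Ttr at 4.62 and 11.89, where other tumour pairs had 140 to 859 and dorsal pairs 11 to 333. The shared chip is argued against, since tumour 10 on that chip correlated with them at 0.898 or less, below the median of 0.918 of pairs outside these tumours. A gained region around Kmt2b in both tumours is a candidate explanation for part of the likeness. Over the 10 nearest neighbours of Kmt2b, the median difference from the median of the other 6 tumours was 2.64 in tumour 8 and 2.87 in tumour 9. Both lay at percentile 99.97 of 11532 windows. The 99th percentile was 0.779 and 0.759. Kmt2b was picked for its high signal in these tumours, and how much of the likeness over all genes the region accounts for was not tested. Both tumours may then share an origin, as may tumours 6 and 7, for which this was not tested, and the number of independent tumours may be under 8; with them averaged 6182 genes passed against the mean of both controls.

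Other groupings of the same arrays were counted for each comparison. For tumour against the mean of both controls chance is argued against, as only 1 of 100 groupings, the real one, gave as many genes. The real one gave 6348 against 3576 in the highest other, 3070 against 1904 at 2-fold, and 3867 against 450 for genes called against both regions. The highest other grouping left 1 tumour among those labelled tumour and so nearly mirrors the real one, which is a structure of the samples. Chance is likewise argued against for dorsal control, with 5890 genes against 1787 and 3242 against 1150 at 2-fold. For ventral control it is too, with 4784 against 712 and 2942 against 462 at 2-fold, each reached by 1 of 100 groupings. For ventral against dorsal control chance is argued against as well, with 1111 genes against 262 and 737 against 209 at 2-fold. Only the real one of 56 groupings gave as many, and 1 of 56 is the lowest share this count can reach. For the number of called lists chance cannot be excluded, since 27 of 100 groupings gave at least the 14 lists of the tumours, with up to 18, and 18 of 56 gave at least the 6 lists of the controls, with up to 9.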
